A study of Homo sapiens with 12 samples.

How the data were processed

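Regulatory T cells from 6 healthy donors had been isolated by flow cytometry and kept in culture overnight with interleukin 2 and OKT3, an antibody against CD3 that triggers the T cell receptor. Each donor's cells were cultured without and with zoledronic acid (ZA), so the 12 libraries form 6 donor pairs, 6 libraries per arm, and the replicate number is the donor number. Per the labels' protocols, RNA was purified from lysed cells with a column kit for small samples and libraries were made with a Clontech SMARTer kit whose version is not stated. The design entry names the Illumina HiSeq2500.

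The deposited tables hold raw read counts per gene, 1 table per library, with no normalization visible in the values. Per the submitters' processing notes, base calls came from CASAVA 1.8, read quality was checked with FastQC 0.11.4, reads were aligned with STAR to hg19/GRCh37, and edgeR was named without a statement of its use. The versions of STAR and of the gene annotation are not stated. Each table has 57783 gene rows with versioned Ensembl identifiers, 4 summary rows, and 3 count columns in STAR's usual layout, in which the first ignores strand and the others count each strand. The strand columns were nearly equal in every library (ratio 1.02), so the column that ignores strand was used. Reads of genes that overlap on opposite strands can therefore not be separated. The tables contain 0 rows for mitochondrially encoded genes, so the share of mitochondrial counts that had been planned as a quality measure could not be computed.

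Gene symbols were matched through the identifiers without version; 90.5% of rows had a symbol. The reference annotation in the box is of another build (GRCh38), so no coordinates are given, and it was used only for symbols, gene classes, gene length and GC content. Of the entries in the pathway lists, 47 (8.59%), which hold 38 distinct genes, could not be tested, most because their counts were too low. ORAI1 and UHRF1 were among them because their identifiers differ between annotation versions. The oxidative phosphorylation genes listed as ATP5A1, ATP5B, ATP5C1 and ATP5O were found under their current symbols. Rows for XIST, TSIX and chromosome Y were removed before library sizes were computed.

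Summary rows stayed out of the library sizes. Library totals ranged from 13057490 to 20918203 gene counts. Genes were kept by edgeR's filterByExpr by arm, which left 15455 genes. Counts were scaled by TMM and tested with the quasi-likelihood F-test of edgeR 4.0.16 with the donor as a block, in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg over all tested genes with a threshold of 0.05. The prior degrees of freedom of this fit were 14.1. The block was used because the design states that cells of the same donors were cultured in both arms. Deviations from the arm means were correlated across genes within each donor pair at 0.392 to 0.583, and for 6 of 6 donors the no-ZA library correlated best with the same donor's ZA library; the highest correlation between libraries of different donors was 0.262. The biological coefficient of variation was 0.109 with the block and 0.240 without it. Fold changes are given on the log2 scale as ZA over no ZA with standard errors or 95% intervals, and expression is given as TMM-scaled CPM, mean ± SD over 6 libraries.

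There were 22 gene lists and 10 marker lists of other cell types, written before the data were examined, as were the tests, the alternatives and the rule for named genes. Lists were tested on logCPM (prior count 2) with limma 3.58.1 camera, two-sided, with the donor as a block and a preset inter-gene correlation of 0.01, adjusted over the 22 lists. Beside it stand camera with an estimated correlation, fry, and a score per donor, which is the mean log2 difference of the list members within that donor. Donor scores, library measures and marker sums were tested with exact sign-flip permutation tests over 6 donors, two-sided, whose smallest possible p is 0.03125. After adjustment over a family of lists or measures, a single one at that floor would not pass. Most of a family would have to reach the floor together for any to pass. These tests therefore exclude no difference of 1 or of a few lists or measures. The named genes were to be those past the threshold with the same sign in 6 donors. Where fewer than 5 qualified in a direction, the 8 genes with the smallest p in that direction and a mean logCPM of at least 3 were given as values without being called changed. Genes of the mevalonate, NFAT, interleukin 2 and regulatory T cell programmes chosen in advance, and the members of each list with the smallest p, were named in addition. Genes that differ mostly by genotype were not named, and some genes of the rule are not reported here.

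The fit was tested on simulated counts drawn from the real means and library sizes, with 200 of 15455 genes changed in each of 5 data sets. With the block, 38.4% of genes changed 1.25-fold, 61.2% of those changed 1.5-fold and 80% of those changed 2-fold were called, and 5.29% of calls were false. Without the block 1.6%, 29.2% and 60.4% were called. In 20 simulated lists of 25 genes shifted 1.1-fold, 100% passed an unadjusted p of 0.05 by camera with either correlation and by the sign-flip test. The simulated genes varied independently of each other, unlike real list members. The genes of the simulated lists were drawn from those with a mean count above 200, so lists with many genes of low count were not covered. The real lists were judged on p-values adjusted over all lists, so these shares do not give the power of the adjusted tests.

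Alternatives were a fit without the block, edgeR's RLE size factors, upper-quartile scaling, no count filter, a stricter filter (CPM of at least 5 in 6 libraries), DESeq2 1.42.0, limma voom with and without sample weights, a robust prior, a strand column, thinning to equal depth, removal of ribosomal protein and haemoglobin genes, 1 surrogate variable from sva 3.50.0, corrections for GC content and gene length (98.6% of tested genes had values), a test against a 1.2-fold change, a prior count of 0.5, and leaving out each donor pair. After the data were seen, the share of reads outside annotated genes as a covariate, removal of the 2 donor pairs with the largest change in that share, and lists tested against protein-coding genes alone were added; what the last would show was written down before it was run. Donors were also exchanged between arms in all 32 ways that keep the pairs, and 100 splits of the 12 libraries were fitted without the block. Intervals of summed counts cover counting error only, since amplified reads are not independent molecules.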

Results

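RNA was sequenced from human regulatory T cells of 6 donors after overnight culture with interleukin 2 and an anti-CD3 antibody, without or with ZA, a bisphosphonate that inhibits farnesyl diphosphate synthase of the mevalonate pathway. There were 6 libraries per arm, and each donor contributed 1 library to each. Library totals ranged from 14396031 to 19959255 gene counts without ZA and from 13057490 to 20918203 with ZA. Both arms carried the transcripts of regulatory T cells. FOXP3, the lineage's transcription factor, stood at 429 ± 87.5 CPM without ZA and 422 ± 78.0 CPM with ZA (SD, n = 6), and IL2RA, the high-affinity interleukin 2 receptor chain, at 492.8 ± 127 and 487 ± 153 CPM. The T cell gene CD3E stood at 381 ± 69.2 and 373 ± 42.6 CPM, and CD4 at 307 ± 54.1 and 293 ± 36.7 CPM.

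The main comparison asked which transcripts ZA changed, in particular those of NFAT and interleukin 2 signalling, which the series names. No single gene passed the test. With edgeR and the donor as a block, 0 of 15455 genes rose and 0 fell with ZA, and the lowest adjusted p was 0.904. At an unadjusted p under 0.05 there were 846 genes, 537 higher and 309 lower, where chance gives 772.75; the split was 396 higher and 532 lower with a correction for GC content, and 412 and 416 with one for gene length. DESeq2 called 0 genes (659 at an unadjusted p under 0.05), limma voom 0 (831), and edgeR without the block 0 (198). The fit was narrow for well expressed genes: of 9589 genes with a mean logCPM of at least 3, 98.8% had a 95% interval that lay within a 1.5-fold change in either direction. The same direction in all 6 donors was seen for 452 genes (2.92%), where chance gives 3.125%. Without replicate 5, 1 gene passed, and edgeR run with no count filter called 42 genes, 40 higher and 2 lower.

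ZA's direct target and the genes that respond to sterol shortage differed little between arms, and the 95% intervals of FDPS, HMGCS1, INSIG1, SQLE and IDI1 included 0. FDPS (ENSG00000160752.10), which encodes the enzyme ZA inhibits, stood at 22.5 ± 1.90 CPM without ZA and 21.04 ± 1.72 CPM with it. Its log2 fold change was -0.095 (95% interval -0.26 to 0.074, edgeR adjusted p 0.921), and it was lower in 6 of 6 donors. HMGCS1 (ENSG00000112972.10), driven by SREBP2 when sterols run short, had a log2 fold change of 0.0047 (-0.16 to 0.17), so its interval excluded a rise above 1.12-fold. INSIG1, also an SREBP2 target, had a log2 fold change of -0.018 ± 0.063 (SE), SQLE 0.077 ± 0.077 and IDI1 -0.087 ± 0.060. Of 27 measured genes of sterol synthesis and uptake, 11 were higher and 16 lower, and the list did not pass camera (adjusted p 0.578). The members with the smallest p were IDI1, EBP and HSD17B7, with log2 fold changes of -0.087, -0.087 and -0.10. Among 19 enzymes of isoprenoid synthesis and prenylation, 6 were higher and 13 lower (camera adjusted p 0.213). ICMT, which methylates prenylated proteins, had the smallest p there with a log2 fold change of -0.15 ± 0.078. Of 7 measured oxysterol and LXR targets, 5 were lower (camera adjusted p 0.161), LPCAT3 by the smallest p with a log2 fold change of -0.14 ± 0.078. RHOB was below the count filter, with 34 counts in total over the no-ZA libraries and 46 over the ZA libraries.

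**Figure D1:**
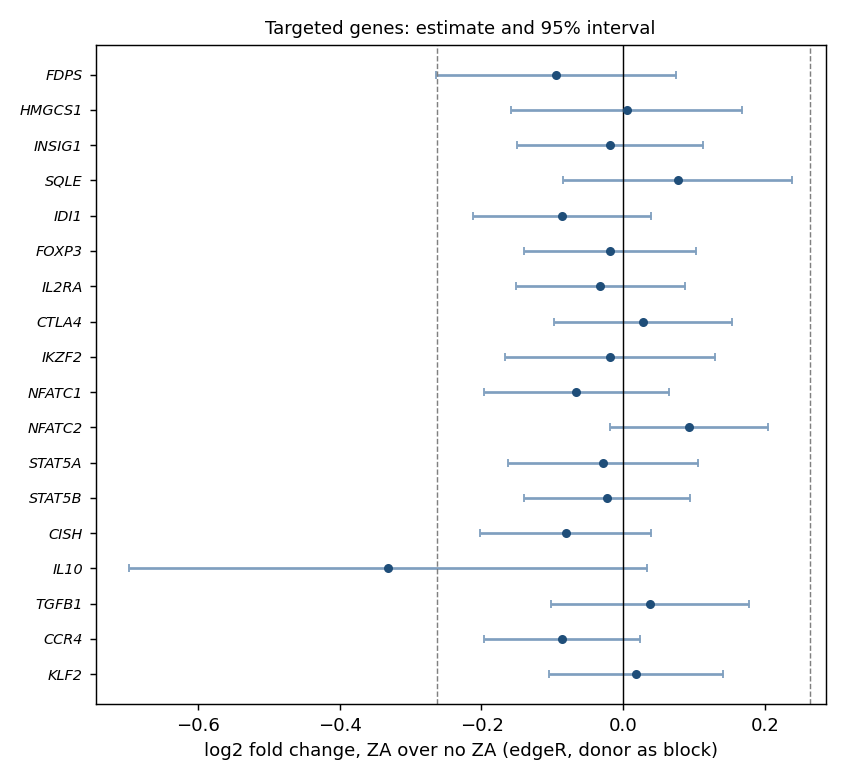
Log2 fold change of 18 genes chosen in advance (x axis, ZA over no ZA, edgeR with the donor as a block, 6 donors), with points for estimates, bars for 95% intervals and dashed lines at a 1.2-fold change. Every interval crosses 0, and that of IL10 is the widest, from -0.70 to 0.034.

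Targets of NFAT, the calcium-dependent transcription factor of T cell activation, leaned lower without a gene that passed. Of 25 measured targets, 18 were lower and 7 higher, with a median log2 fold change of -0.066. The member with the smallest p was TNFRSF9, the costimulatory receptor 4-1BB, at 16.7 ± 5.55 CPM without ZA and 14.3 ± 5.70 CPM with it, lower in 6 of 6 donors, with a log2 fold change of -0.25 ± 0.099 and an edgeR adjusted p of 0.904. NR4A1, an early response gene, was also lower in 6 of 6 donors, at -0.28 ± 0.15. The list passed camera with the preset correlation (adjusted p 0.0156) and did not with an estimated correlation (adjusted p 0.440) or against protein-coding genes alone (adjusted p 0.0770). As a donor score the NFAT targets averaged -0.11 ± 0.16 (SD), lower in 5 of 6 donors (exact sign-flip p 0.0938, adjusted p 0.645). Replicate 5 had a score of -0.42; without replicate 5 the mean score was -0.043, and the list did not pass camera with the preset correlation either (adjusted p 0.521). The 27 components of the pathway itself showed no lean, with 15 higher and 12 lower (camera adjusted p 0.525). Among them NFATC2 (ENSG00000101096.15) had a log2 fold change of 0.092 ± 0.053 and was higher in 6 of 6 donors, NFATC1 one of -0.066 ± 0.062, NFAT5 one of 0.23 ± 0.096, and LCK, the kinase that starts receptor signalling, one of -0.11 ± 0.056. IL2 itself had counts in a single library, 3 without ZA against 0 with ZA over the arms.

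Genes induced by interleukin 2 through STAT5 leaned lower together by small amounts. Of 30 measured, 28 were lower and 2 higher, with a median log2 fold change of -0.081. The list had the lowest camera p of all 22 (adjusted p 0.000131 with the preset correlation), but the adjusted p was 0.440 with an estimated correlation. Its donor score averaged -0.10 ± 0.16 (SD), lower in 4 of 6 donors (exact sign-flip p 0.188, adjusted p 0.645), with -0.38 in replicate 5. Without replicate 5 the mean score was -0.050 and the camera adjusted p 0.176. The examples with the smallest p were GZMB, the cytotoxic protease granzyme B, at 7.03 ± 7.45 CPM without ZA and 3.86 ± 4.01 CPM with it (log2 fold change -0.79 ± 0.34, lower in 5 of 6 donors; -0.48 ± 0.32 without replicate 5), CDKN1A at -0.26 ± 0.12, OSM at -0.17 ± 0.081 and MYC at -0.11 ± 0.054. CISH (ENSG00000114737.11), a feedback inhibitor induced by STAT5, had a log2 fold change of -0.081 (-0.20 to 0.040). The receptor and its transducers were close to 0, with IL2RA (ENSG00000134460.11) at -0.033 (-0.15 to 0.087), STAT5A at -0.029 ± 0.064 and STAT5B at -0.023 ± 0.056. The 19 pathway components were 15 lower and 4 higher (camera adjusted p 0.0650); MTOR at 0.11 ± 0.061 and PIK3R1 at -0.096 ± 0.058 had the smallest p.

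No single gene of the regulatory T cell programme passed the test, and the lineage's main genes differed little between arms. FOXP3 (ENSG00000049768.10) had a log2 fold change of -0.019 (-0.14 to 0.10), which excludes a fall below 0.907 of the level without ZA. CTLA4, an inhibitory receptor used in suppression, had one of 0.028 ± 0.060, IKZF2 one of -0.019 ± 0.071 and TGFB1 one of 0.038 ± 0.067. The suppressive cytokine IL10 varied most, at 10.1 ± 11.95 CPM without ZA and 9.86 ± 15.6 CPM with it (log2 fold change -0.33 ± 0.17, edgeR adjusted p 0.908). That IL10 value was -0.040 without the block and ran from -0.51 without replicate 1 to -0.20 without replicate 5, with -0.21 without replicate 4. The chemokine receptor CCR4 was lower in 6 of 6 donors by a small amount, with a log2 fold change of -0.087 ± 0.053, and KLF2, which controls homing receptors, was at 0.018 ± 0.059. Of 29 measured signature genes, 21 were lower and 8 higher; camera gave an adjusted p of 0.0110 with the preset and 0.440 with an estimated correlation, and 0.0645 against protein-coding genes alone. CCR8 and LRRC32, the latter a carrier of latent TGF-beta, followed TNFRSF9 with log2 fold changes of -0.18 ± 0.091 and -0.12 ± 0.063.

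Most other lists also leaned lower. In all, 14 of the 22 lists were lower and 1 higher past the camera threshold with the preset correlation, and 0 with an estimated correlation, where the lowest adjusted p was 0.440. Against protein-coding genes alone, 3 of the 14 stayed lower past the preset threshold (IL-2 and STAT5 targets, glycolysis and mitotic genes), and the 1 higher list stayed. The lists' own log2 changes are the same in that test, where only the genes they are set against differ. Without the block 4 lists were lower and 1 higher, and 0 of 22 donor scores passed the exact sign-flip test (lowest adjusted p 0.645). Without replicate 5, 1 list was lower past the preset threshold, and without replicate 2, 6 were. The fry test, which asks whether a list's members move one way on balance, passed for 0 lists (lowest adjusted p 0.481). No member of any list passed when adjusted over the list alone or over all genes. Glycolysis and hypoxia genes were lower in 22 of 25 cases (adjusted p 0.000192 preset, 0.440 estimated), with P4HA1 at -0.18 ± 0.078 and ALDOC at -0.21 ± 0.097. Mitotic genes were lower in 18 of 25 (0.00745 preset, 0.440 estimated), with ASPM at -0.33 ± 0.11 and KIF11 at -0.27 ± 0.098, and S phase genes in 19 of 25 (0.0110 preset, 0.440 estimated), with RRM1 at -0.14 ± 0.067. NF-kB targets were lower in 15 of 19 (0.0187 preset, 0.440 estimated); NFKBIE, a feedback inhibitor of NF-kB, was lower in 6 of 6 donors at -0.25 ± 0.082, while BCL2A1, a survival gene, was higher in 6 of 6 at 0.27 ± 0.14. Small GTPases that carry a prenyl group were lower in 21 of 23 (0.00986 preset, 0.440 estimated), with CDC42 at -0.11 ± 0.057. The remaining lists past the preset threshold were immediate early genes (18 of 24 lower), the unfolded protein and integrated stress response (19 of 25), homing receptors (21 of 23), oxidative phosphorylation (20 of 21), effector cytokines (10 of 14) and p53 targets (16 of 25), with adjusted p between 0.00986 and 0.0469 for the preset correlation and of 0.440 to 0.447 for an estimated one. Heat shock genes (13 of 14 lower) and actin and cytoskeleton genes (14 of 21 lower) did not pass, with adjusted p of 0.0650 and 0.153.

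The lean toward lower lists was unevenly shared among donors and moved with a library measure. The share of reads outside annotated genes was 19.1 ± 4.10% without ZA and 21.6 ± 2.15% with ZA (SD, n = 6; exact sign-flip p 0.313). Within donors it changed by 3.72 to 8.84 points in 3 donors and by -2.31 to -1.27 points in the other 3. Across the 6 donors the mean score of the 14 lower lists went down as this share went up (Pearson r = -0.80, exact permutation p 0.0375; Spearman rho = -0.89, exact permutation p 0.0333; adjusted over 4 relations 0.131 and 0.133). Without the 2 donors farthest from the median change, r was -0.52, so the relation rests on them. In the 3 donors whose share was higher with ZA than without, the mean score was -0.14 ± 0.064 (SE), and in the others 0.00013 ± 0.027. With the share as a covariate, or without replicates 2 and 5, 0 lists were lower past the threshold. Leaving out replicates 2 and 5 is no independent test of the share. They also had the 2 lowest mean scores of the 14 lists, -0.12 and -0.26, so their removal weakens the lean whatever its cause.

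**Figure D2:**
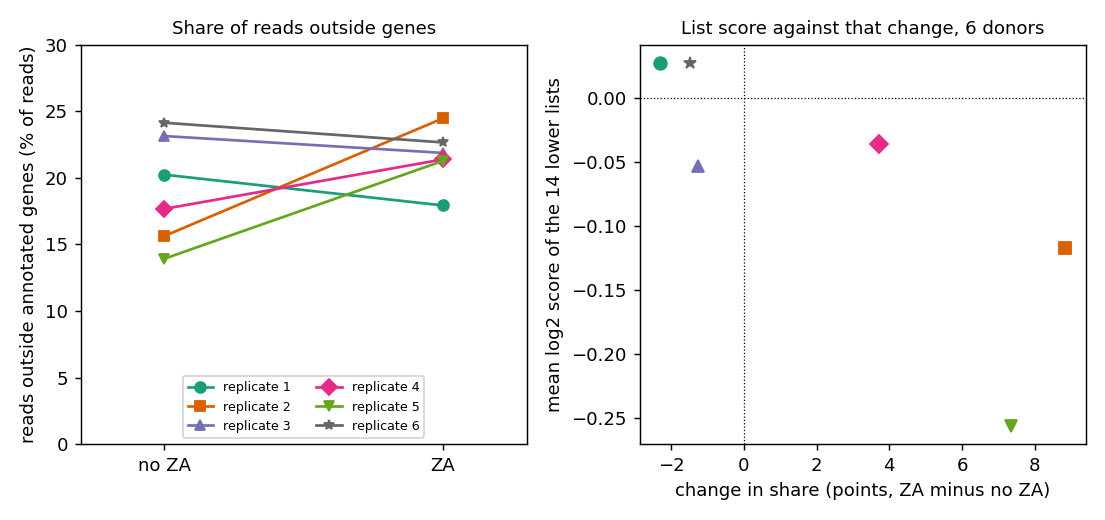
Left, share of reads outside annotated genes in each library (percent of reads), with a line per donor from no ZA to ZA. Right, mean log2 score of the 14 lower lists against the change in that share (percentage points), 1 point per donor; replicate 5 has the lowest score, and replicates 2 and 5 the largest changes, 8.84 and 7.35 points.

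Interferon response genes were the list that leaned higher. Of 33 measured, 28 were higher and 5 lower, with a median log2 fold change of 0.092 (camera adjusted p 0.000192 with the preset correlation, adjusted p 0.440 with an estimated correlation). The donor score averaged 0.14 ± 0.29 (SD) and was positive in 5 of 6 donors (exact sign-flip p 0.25, adjusted p 0.645); replicate 5 stood at -0.39. IFI44L, an antiviral response gene, stood at 2.29 ± 1.37 CPM without ZA and 4.81 ± 3.57 CPM with it, with a log2 fold change of 0.95 ± 0.31; it was 1 of 2 list members that rose past the threshold in the fit with no count filter (edgeR adjusted p 0.0223). XAF1, which had the smallest p of the list, was at 0.25 ± 0.071, CMPK2 at 0.43 ± 0.16 and EPSTI1 at 0.27 ± 0.11, each with an edgeR adjusted p of 0.904. The preset camera call ended without replicate 1 (adjusted p 0.0879).

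**Figure D3:**
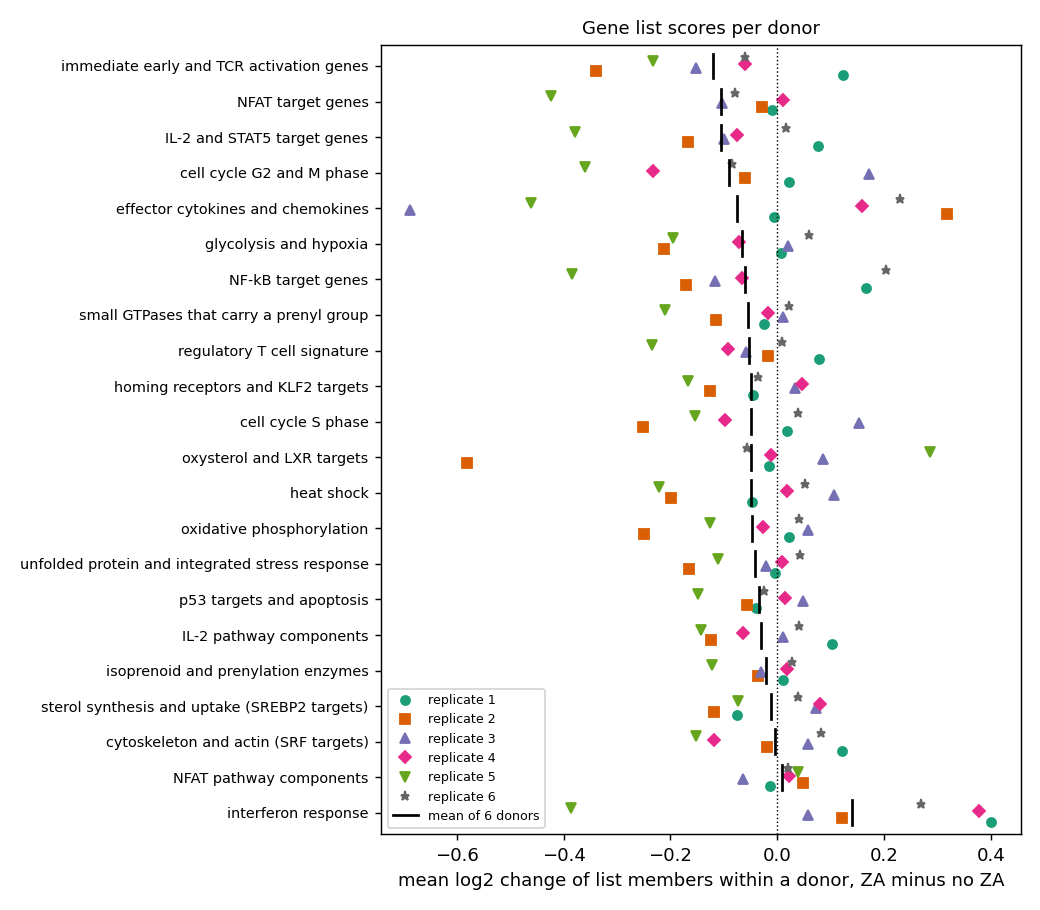
Mean log2 change of the members of each of the 22 gene lists within each donor (x axis, ZA minus no ZA), with 1 symbol per donor and a black bar at the mean of 6 donors. The interferon list averages 0.14 with replicate 5 at -0.39, and the NFAT target list averages -0.11 with replicate 5 at -0.42.

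The genes with the smallest p by the rule fixed in advance are given as values, since none passed (edgeR adjusted p 0.904 for each). Higher with ZA were CTNND1, which encodes the cadherin partner p120 catenin, at 11.8 ± 2.53 CPM without ZA and 16.3 ± 2.79 CPM with it (log2 fold change 0.48 ± 0.11, 6 of 6 donors), UBR4, a ubiquitin ligase (0.30 ± 0.074, 6 of 6), and RNF213, an interferon-inducible ubiquitin ligase (0.25 ± 0.068, 5 of 6). TAFA2, STARD9, SLC37A1, FHIT and FAM185A had log2 fold changes between 0.38 and 0.47. Lower with ZA were AARS2, the mitochondrial alanyl-tRNA synthetase, at 44.8 ± 5.49 CPM without ZA and 36.1 ± 2.88 CPM with it (log2 fold change -0.31 ± 0.077, 6 of 6 donors), PAFAH2, a phospholipase (-0.32 ± 0.082, 6 of 6), and IKZF3, the lymphoid transcription factor Aiolos (-0.25 ± 0.072, 5 of 6). NXPE3, ZNF527, TRMT2B, NCEH1 and NCKIPSD had log2 fold changes between -0.42 and -0.22.

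Most of the variance of logCPM lay between donors, 69.3%, where unrelated labels give 45.5%. Between arms lay 6.13%, where exchanges of arms within donors give 5.12% on average. Each donor's log2 changes were correlated across genes, which are not independent replicates, with the mean of the other 5 donors at -0.090 to 0.25, with a median of 0.074. This r was 0.20 to 0.25 in the 3 donors whose share of reads outside genes was higher with ZA, and -0.090 to -0.049 in the other 3. Over genes with a mean logCPM of at least 5 the median was 0.00041. Markers of other cells showed no difference between arms that passed the exact sign-flip test (lowest adjusted p 0.625 over 10 marker lists). Markers of gamma delta T cells, which ZA is known to activate, summed to 6.73 ± 1.02 CPM without ZA and 6.95 ± 1.49 CPM with it. CD8 T cell markers summed to 1.85 ± 0.949 and 2.14 ± 1.68 CPM, monocyte and macrophage markers to 7.997 ± 3.71 and 7.55 ± 2.79 CPM, dendritic cell markers to 1.29 ± 0.718 and 1.26 ± 1.01 CPM, and B cell markers to 56.4 ± 11.4 and 54.7 ± 10.8 CPM, mostly CD79B (36.8 and 34.3 CPM) and FCRL1 (15.0 and 16.1 CPM). NK cell markers summed to 242 ± 49.6 and 223 ± 40.1 CPM, of which PRF1, also expressed by activated T cells, made up 167 and 149 CPM and NCR3 68.0 and 67.5 CPM. Markers of conventional CD4 T cells summed to 1233 ± 281 and 1161 ± 201 CPM, mostly CCR7 (772 and 707 CPM), IL7R (221 and 219 CPM) and TCF7 (202 and 197 CPM). These sums cannot tell conventional CD4 T cells beside the sorted cells from expression by the regulatory T cells themselves, so such cells stay possible. Erythroid, platelet and neutrophil markers summed to 0.360, 1.73 and 5.19 CPM without ZA and 0.538, 1.72 and 3.35 CPM with it. Over 9 library measures the lowest adjusted p was 0.884.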

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

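The tests against reads outside genes, the contrast of the lists with the genes they are set against, the test of an equal response in every donor and the test of unspliced RNA were chosen after the result was seen. The test against protein-coding genes alone was added after the data were seen, with its outcome not yet known. In 181 groups of 6 values, 14 held a sample far from the others by Dixon's test, where chance flags about 1 in 20.

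Among libraries without ZA, gamma delta T cell markers were lowest in replicate 4, at 4.75 CPM against 6.87 CPM in the next, a gap of 0.722 of the range. HMGCS1 was highest in replicate 3, at 45.7 CPM against 35.2 CPM (0.694 of the range). STAT5A was highest in replicate 5, at 364 CPM against 296 CPM (0.881). IL10 was highest in replicate 1, at 34.2 CPM against 7.42 CPM (0.833), and the same donor led with ZA, at 41.6 CPM against 5.04 CPM (0.938). Among libraries with ZA, CD8 T cell markers were highest in replicate 5, at 5.37 CPM against 2.47 CPM (0.654), and SQLE in replicate 3, at 59.7 CPM against 42.2 CPM (0.642). Replicate 1 with ZA had the highest mean logCPM of NFAT targets (4.32 against 3.33; 0.833), NF-kB targets (5.66 against 5.33; 0.779), heat shock genes (6.89 against 6.69; 0.679) and actin and cytoskeleton genes (6.91 against 6.63; 0.638). The mean logCPM of p53 targets with ZA was lowest in replicate 5, at 6.18 against 6.24 (0.627). Among donor changes, the share of ribosomal protein counts was lowest in replicate 2, at -0.71 points against -0.059 points (0.686). The NFAT target score was lowest in replicate 5, at -0.42 against -0.10 (0.737).

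The 14 lists that were lower and the 1 that was higher past the preset camera threshold are a first pattern. Chance cannot be excluded: 4 of the 32 exchanges of arms within donors, the real one included, put as many lists past the threshold, with 15 for the real arms and 15 as the highest other. More reads outside annotated genes in the ZA library of some donors is consistent with the lean (r = -0.80 across 6 donors). The presence of other gene classes in the comparison set stays open: 3 of the 14 lower lists stayed past the threshold against protein-coding genes alone, but the mean log2 contrast of the 14 with the other genes went only from -0.10 ± 0.068 (SE over 6 donors) to -0.065 ± 0.041. The lists did not move, and the mean of the genes they are set against went from 0.035 to -0.0036. A response to ZA of the same size in every donor stays open: the donors with the smallest change in that share scored 0.14 ± 0.070 (SE of the difference) above the other 3. The 2 library explanations and a ZA effect in some donors only cannot be separated with 6 donors.

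A second pattern lies in the gene classes that moved with the share of reads outside genes. In the 3 donors whose share was higher with ZA, the median log2 change was 0.63 ± 0.19 (SE over donors) for 166 sense intronic genes, 1.03 for 42 T cell receptor joining segments, 0.40 for 971 antisense genes and -0.054 for 11779 protein-coding genes, while in the other 3 donors the sense intronic median was -0.13. Genomic DNA in the libraries may contribute: 505 olfactory receptor, taste receptor, keratin-associated and beta-defensin genes, nearly silent in T cells, were 1.34-fold higher with ZA in those 3 donors (95% interval 1.23 to 1.46, from 1150 and 917 counts) and 0.936-fold (0.863 to 1.01) in the others. Both intervals cover counting error only, not the spread between donors. By donor the fold of the silent genes ran from 1.24 to 1.44 in those 3 donors and from 0.83 to 1.17 in the others. Unspliced RNA in the libraries stays open as well, since the sense intronic median of 0.63 exceeded the change of the silent genes by less than 2 of its standard errors. The joining segments, at 1.03 ± 0.080, exceeded that change by more than 2 of theirs. Antisense genes (0.40 ± 0.11), lincRNA (0.26 ± 0.074) and processed pseudogenes (0.34 ± 0.077) did not. A rise of genomic DNA by the fold of the silent genes would thus not cover the joining segments by itself. The design gives no biological explanation of this pattern that was tested.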

How the results depend on the processing

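The count of 0 genes held under 21 of 24 other fits. With no count filter 42 genes passed, 40 higher and 2 lower (GZMB and MATCAP2, named after their values were seen), and 2 of the 40 were of the interferon list, IFI44L among them. That fit's prior degrees of freedom became infinite against 14.1 in the main fit, so every gene was given the spread of its abundance class, 0.925 in place of 2.73 for GZMB; 42 of the 42 genes were also tested in the main fit. Leaving out 1 donor gave 0 to 1 genes changed, 0 to 1 higher; the 1 came without replicate 5. Without the 2 donors with the largest change in reads outside genes, 4 genes passed, all 4 higher, GBP4, TAP1 and GBP1 among them. Replicate 5, left out there, had the lowest change of GBP4, TAP1 and GBP1 (-0.80, -0.42 and -0.84). Without the replicate block, 5 lists passed in place of 15, 4 of them lower, NFAT targets had a camera adjusted p of 0.127, and HMGCS1 turned to -0.0043; the block changed no other call among genes, where both fits gave 0. GC correction turned the split at an unadjusted p under 0.05 to 396 higher and 532 lower, and length correction to 412 and 416, from 537 and 309.

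With an estimated inter-gene correlation 0 lists passed, 0 lower and 0 higher, and both NFAT targets and IL-2 and STAT5 targets had an adjusted p of 0.440. Against protein-coding genes alone 4 lists passed, 3 lower, NFAT targets had an adjusted p of 0.0770, and sterol synthesis turned higher (0.830). With no count filter NFAT components turned lower (0.944). With the share of reads outside genes as a covariate 1 list passed and 0 lower, IL-2 and STAT5 targets had 0.316 and NFAT targets 0.265, and 6 lists turned higher: IL-2 components (0.511), S phase (0.854), cytoskeleton (0.511), heat shock (0.582), oxidative phosphorylation (0.582) and sterol synthesis (0.582). Without the 2 donors with the largest change 1 list passed and 0 lower, IL-2 and STAT5 targets had 0.770 and NFAT targets 0.478, and 11 lists turned higher: IL-2 components (0.317), S phase (0.776), cytoskeleton (0.257), glycolysis (0.932), heat shock (0.257), homing receptors (0.983), prenylation enzymes (0.932), oxidative phosphorylation (0.372), small GTPases (0.776), sterol synthesis (0.431) and the unfolded protein response (0.932).

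Over the fits that each leave out 1 donor, 2 to 17 lists passed, 1 to 16 lower and 0 to 1 higher, with camera adjusted p of 2.42e-06 to 0.176 for IL-2 and STAT5 targets, 0.00316 to 0.521 for NFAT targets and 0.233 to 0.926 for sterol synthesis, whose direction turned. Log2 fold changes that changed sign ran from -0.018 to 0.054 for CTLA4, -0.063 to 0.011 for FOXP3, -0.039 to 0.070 for HMGCS1, -0.11 to 0.022 for IKZF2, -0.062 to 0.011 for INSIG1, -0.019 to 0.060 for KLF2, -0.069 to 0.027 for STAT5A, -0.055 to 0.0061 for STAT5B and -0.016 to 0.085 for TGFB1, none past the threshold. The cause of these changes was not tested, beyond the fewer samples of these fits. Median donor scores and mean logCPM of markers passed no test either, library measures without 1 donor could not pass one with 5 donors, and 304 of 322 fold changes of named genes kept their direction. Depth limits genes of low count such as IL2, RHOB and IFNG.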

Other observations

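The tests of the interferon list against arm exchanges, reads outside genes and IFNG, and the genes named here, were chosen after their values were seen; the test against monocyte and dendritic cell markers was written before. In 5 of 6 donors interferon response genes stood higher with ZA. GBP1 and GBP4 encode guanylate-binding proteins, and TAP1 the peptide transporter of antigen presentation. Over 6 donors their log2 fold changes were 0.13 ± 0.12, 0.15 ± 0.12 and 0.13 ± 0.078 (edgeR adjusted p 0.924, 0.921 and 0.914). In replicate 5 they changed by -0.84, -0.80 and -0.42. Without replicate 5 the log2 fold changes were 0.31 ± 0.076, 0.32 ± 0.079 and 0.23 ± 0.056 (edgeR adjusted p 0.918 each). Of the fits tried, only the one without replicates 2 and 5 put these genes past the threshold, with log2 fold changes of 0.39, 0.43 and 0.28 (edgeR adjusted p 0.0230, 0.00134 and 0.00628). That is no independent test, since replicate 5, left out there, had the lowest change of each gene. IRF1 passed in none. Without replicate 5 the list's mean score was 0.24 ± 0.15 (SD), which is no independent test since replicate 5 was the 1 donor with a negative score, and camera gave an adjusted p of 6.29e-20 with the preset and 0.308 with an estimated correlation.

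IFNG itself was scarce, at 0.596 ± 0.316 CPM without ZA and 0.866 ± 0.483 CPM with it. Its log2 change was positive in 4 donors, with a highest value of 1.74, and -3.08 in replicate 5. GZMB was lower with ZA in 5 of 6 donors, from 1.85 to -2.49, with a log2 fold change of -0.79 ± 0.34 (edgeR adjusted p 0.904) that was -0.48 ± 0.32 without replicate 5.

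For the interferon list, chance cannot be excluded: 8 of the 32 exchanges of arms within donors, the real one included, gave a mean score as far from 0, with 0.14 for the real arms and 0.27 as the highest other. More reads outside genes did not go with a higher interferon score (r = -0.54 across 6 donors, exact permutation p 0.253). That r turned to 0.29 without the 2 donors farthest from the median change in share, so it decides nothing. With that share as a covariate the list's mean log2 change was 0.22 in place of 0.14. The list stayed past the preset camera threshold there (adjusted p 8.17e-15), but that p cannot decide either. In the main fit the list did not pass camera with an estimated correlation (adjusted p 0.440). Exchanging the arms of replicate 5 alone gave an unadjusted camera p of 2.1e-30 for this list. That exchange turns the 1 negative donor score positive and keeps the other donors, so its p is no example of chance. The other exchanges with a mean score as far from 0 as the real one all exchanged replicate 5 too. In replicates 1, 3 and 6, whose share was lower with ZA, the interferon score was still positive, at 0.40, 0.057 and 0.27. These values argue against more reads outside genes as the explanation in those 3 donors. In replicates 2, 4 and 5, whose share was higher with ZA, the score was 0.12, 0.38 and -0.39, and there the explanation stays open. Monocytes or dendritic cells beside the sorted cells stay open (r = 0.28, exact permutation p 0.538). Without the 2 donors farthest from the median marker change that r was -0.49. LYZ, the most abundant marker, stood at 3.71 ± 3.02 CPM without ZA and 2.81 ± 2.54 CPM with it. CSF1R stood at 2.56 and 2.82 CPM and CD14 at 1.54 and 1.76 CPM. Other monocyte markers were close to 0, such as S100A9 at 0.054 and 0.013 CPM and FCN1 at 0.011 and 0.013 CPM. A candidate explanation is a different level of interferon gamma in the 2 cultures of a donor: the score rose with the change of IFNG (Pearson r = 0.85, exact permutation p 0.0653; Spearman rho = 0.77, p 0.103; 0.131 and 0.206 adjusted over 4 relations). Without the 2 donors farthest from the median IFNG change r was 0.60, so this stays open with 6 donors and a transcript of such low count, as does an effect of ZA in some donors only.

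For the 846 genes at an unadjusted p under 0.05 chance cannot be excluded: 9 of the 32 exchanges gave as many, and the highest other gave 2288. For the count of 0 genes past the threshold the exchanges test nothing, since all 32 call at least 0; the highest other called 2. Without the block, 100 splits of the 12 libraries called up to 124 genes against 0 for the real arms. The 2 counts are not alike, because the real arms part all 6 donor pairs, while the splits with the most calls, 124 and 123, parted 0 and 2. Splits that keep pairs together set donors against each other, and 69.3% of the variance lay between donors. These splits therefore test nothing about ZA.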
